A study of Mus musculus with 3 samples.

How the data were processed

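Single-cell RNA was measured by droplet sequencing (10x Genomics, version 2 chemistry, which counts the 3' ends of transcripts with unique molecular identifiers, UMIs) in cells of the aorta-gonad-mesonephros region (AGM) of mouse embryos at E10.5, the part of the embryo where the first haematopoietic stem cells arise from the wall of the aorta. Per the labels, embryos of 28 to 32 somite pairs were pooled and 3 populations were sorted, with 1 sample each. These were live Ter119-negative niche cells, an endothelial gate and a gate for type 1 precursors of haematopoietic stem cells. Both gates took Ter119-negative cells positive for the surface antigens CD31, VE-cadherin and cKit. They differ in the surface antigen CD41, which was negative in the endothelial gate and low in the precursor gate. Each population was spread over 2 lanes, per the labels' protocols. The deposited values are raw UMI counts per gene and barcode, not normalised, in 1 pooled matrix of 27998 genes and 9492 barcodes. Per the submitters' processing notes, Cell Ranger (version not given) and the mm10 build were used. The gene and barcode names deposited by the authors have no measured unit of their own.

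The barcodes carry 8 numeric suffixes, called libraries 1 to 8 here, whereas 3 populations on 2 lanes each would give fewer. No label ties a suffix to a population, so no library was assigned to a sort and the matrix was treated as 1 sample. Libraries entered doublet removal, the check of directions, the alternatives that leave out or reweight them, and values given per library. Whether reads were thinned to equal depth before pooling is not given in the sources used here. With 1 sample per population and no map from cells to populations, no test, p-value or standard error was computed. Intervals are exact Poisson intervals for summed counts and exact binomial (Clopper-Pearson) intervals for shares, at 95%, and cover counting error only.

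Barcodes with at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs were kept (9383 of 9492). Doublets were scored per library from the share of simulated doublets (2 per barcode) among each barcode's neighbours, and the top 5% of each library were removed (468 barcodes), which left 8915. The labels state a doublet rate below 5%. On simulated data this step removed 38 of 87 doublets made by adding barcodes of different classes in library 1, and 31 of 57 in library 5, so doublets remain. Counts were scaled to log values per 10000 UMIs. The 2000 most variable genes were taken after leaving out all genes of the lists to be compared, mitochondrial and ribosomal protein genes and sex-linked genes. Cells were clustered on 30 principal components and 15 neighbours with the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15).

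The 18 marker lists (155 genes), 19 lists of genes to be compared, 50 ligand and receptor pairs, the comparisons, the rule of size and the rule for named genes were fixed before the data were examined. The rule that turns markers into cluster names was not. It was set after the clusters had been seen and went through 4 versions. The thresholds of the rule were chosen in the same way. The first version left cluster 13, the cluster of 252 cells on which the haematopoietic comparison rests, unnamed, and the second was used for exploration only. Version 3, used throughout, asks for at least 3 markers at 20 CPM or more and at least 1 log2 unit above the mean of the other clusters, takes the list with the largest share of such markers, and clusters ambiguous clusters again. It gives priority to the haematopoietic list where at least 0.5 of its markers are raised, even if endothelial markers are raised too. Without that priority the endothelial list would lead in cluster 13, with 9 of 12 markers raised against 8 of 14 haematopoietic ones. Version 3 also clusters again a cluster whose leading genes hold more markers of another class than of its own. The leading genes of cluster 13 hold 1 blood marker and no endothelial one, so it would be clustered again rather than named endothelial. Version 4 was written after version 3 had called the same 252 cells macrophage-like at resolution 2, and is reported only as an added alternative. It gives the same names at the main setting. The 21 clusters became 31 after 3 were clustered again, of which 28 were named, in 16 classes.

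Summed counts of a class were expressed as CPM, the share of the UMIs of the class scaled to the usual CPM total, and classes compared as log2((CPM + 10) / (CPM + 10)). A gene was called higher or lower at an absolute log2 ratio of at least 1, at least 50 CPM in the higher class and the same direction in every library with at least 20 cells of both classes. The named genes were the 8 highest and 8 lowest of the list genes called, up to 4 members of each described list, and the genes of the sorting antigens. For ligands they were the 3 per class with the highest ratio to the next class, and for clusters the 3 members with the largest range in each of the arterial, venous and endothelial-to-haematopoietic lists. A list member counted as measured at 10 CPM or more in either class, and list medians cover measured members only. A list's median log2 ratio was set among 10000 random lists matched on mean expression, as a description of these cells. On simulated counts over 27998 genes, the rule recovered 48 of 50 genes changed 2.5-fold in the haematopoietic comparison and 50 of 50 in the niche comparison, and none of the unchanged genes was called in either. It recovered 0 of 50 genes changed 1.5-fold in either comparison. These counts held Poisson error only. Of 20 unchanged lists, 1 and 3 fell outside the central 95% of random lists. Simulated cells regained their class name in 2422 of 2987 cases; all 150 haematopoietic-like cells did, but their profiles came from the same named cluster. Of the listed genes, 427 of 428 were found in the matrix by symbol, and for the 65 repeated symbols the first entry was used.

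The alternatives fixed beforehand were no doublet removal, a looser and a stricter barcode filter, list genes allowed for clustering, 3000 variable genes, Leiden resolutions of 0.5 and 2, leaving out each library, equal weight per library, a pseudocount of 1 CPM, TMM scaling (a trimmed mean of log ratios), a minimum of 10 CPM and no check of direction. Those chosen after seeing the data were naming version 4, leaving germ-cell-like cells out of the niche, and using only libraries with at least 20 cells of both classes.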

Results

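The series asked how cells of the AGM signal to each other while haematopoietic stem cells emerge. The pooled matrix held 78653331 UMIs over 9492 barcodes, with a median of 7544 UMIs and 2488 genes per barcode. Medians per library were 6548, 7997, 6655, 8639, 6845, 8698, 14725.5 and 15593 UMIs for libraries 1 to 8, and the deposited barcodes numbered 1841, 1661, 1598, 1729, 1230, 1165, 104 and 164. The labels state about 10000 barcodes over all populations. There were no replicate samples, so every value below is 1 sum of counts with its counting error.

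The kept cells were mostly tissue surrounding the aorta. Endothelial-like cells made up 21.9% of the 8915 kept barcodes (95% interval 21.1 to 22.8%, 1956 cells). The niche classes together made up 71.1% (70.2 to 72.1%, 6340 cells), led by mesenchymal-like (1772), neural-like (1529), sclerotome-like (965) and myotome or dermomyotome-like cells (930). Cluster 13, the haematopoietic-like class, held 252 cells or 2.83% (2.49 to 3.19%), and germ-cell-like cells 231 or 2.59% (2.27 to 2.94%). Macrophage-like cells numbered 63, megakaryocyte-like cells 75 and granulocyte-monocyte progenitor-like cells 30, while 189 cells stayed unnamed. These shares are set by the sorts and by how many cells each library held, and do not give the makeup of the tissue.

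**Figure D1:**
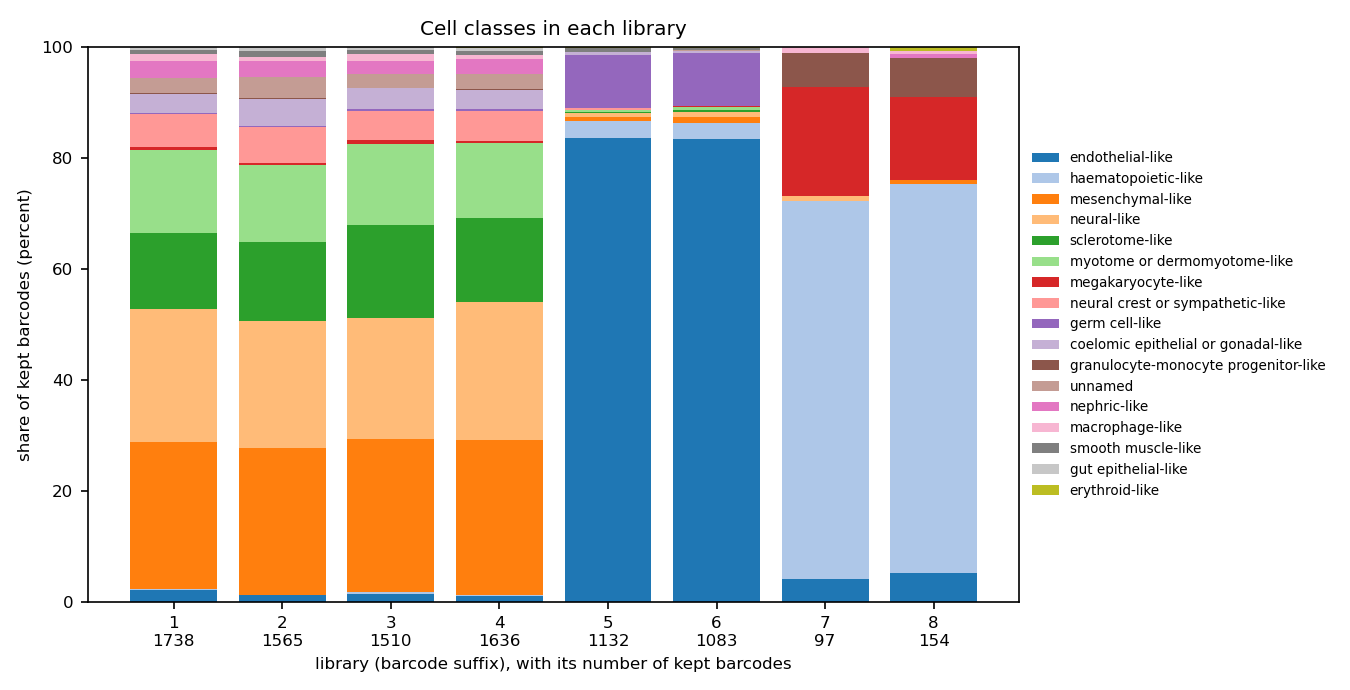
Share of kept barcodes (percent, vertical axis) in each cell class for the 8 libraries (horizontal axis, with the number of kept barcodes); colours stand for classes. Endothelial-like cells made up 83.6% and 83.5% of libraries 5 and 6, and cluster 13 (haematopoietic-like) made up 68.0% and 70.1% of libraries 7 and 8.

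Cluster 13 was compared with the endothelial-like cells to describe cells with blood genes beside the endothelium they are thought to arise from. Of 20 genes of the endothelial-to-haematopoietic list, 9 were called higher in cluster 13 and 11 were not called. Runx1, required for the endothelial-to-haematopoietic transition, stood at 157 CPM (95% interval 144 to 172) against 0.568 CPM (0.26 to 1.08) in endothelial-like cells, a log2 ratio of 3.99. Spi1, the myeloid and lymphoid regulator PU.1, stood at 298 against 0.505 CPM (log2 ratio 4.87). Among genes called lower, Aplnr, the apelin receptor, had no count in cluster 13 (upper limit 1.14 CPM) against 298 CPM, and Kdr, the main VEGF receptor, stood at 34.3 against 477 CPM (log2 ratio -3.46). Of 128 list genes at 50 CPM or more, 19 were called higher and 36 lower, with directions checked in libraries 5 and 6, the libraries with at least 20 cells of both classes. Most cluster 13 cells lay elsewhere, with 174 of 252 in libraries 7 and 8, so the pooled ratios also compare libraries.

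No member of the endothelial-to-haematopoietic list was called lower, and its median log2 ratio was 1.13. Besides Spi1 and Runx1, Ikzf2 reached 163 against 1.89 CPM (log2 ratio 3.86), Bcl11a 128 against 6.06 CPM (3.10), Myb 80.4 against 0.126 CPM (3.16) and Hlf, a factor of stem cells, 79.4 against 0.568 CPM (3.08). The ETS factors Fli1 (log2 ratio -0.39) and Erg (-0.05), shared by endothelium and blood, were not called. Of the cytokine and receptor list, Kit, the receptor for stem cell factor and a gene of the gate, stood at 79.8 against 13.6 CPM (1.92), and Procr, the endothelial protein C receptor, at 60.9 against 19.4 CPM (1.27). Kitl, the ligand of Kit, was lower at 0.309 against 66.7 CPM (-2.89). Angpt1, an angiopoietin, was higher at 95.2 against 1.14 CPM (3.24), and Ifitm1, an interferon-inducible membrane protein, at 406 against 2.97 CPM (5.00).

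The venous list had 7 of 10 measured members lower and 1 higher, with a median log2 ratio of -3.09. Nrp2 stood at 4.02 against 240 CPM (log2 ratio -4.16), Stab1 at 0.927 against 117 CPM (-3.54), Flt4, the lymphatic and venous VEGF receptor, at 1.55 against 121 CPM (-3.50) and Nr2f2, the factor that sets venous identity, at 0.309 against 86.1 CPM (-3.22). Dab2 (-2.96) and Efna1 (-2.94) complete the 8 lowest genes. Vwf, the von Willebrand factor of endothelium and platelets, was the member called higher (83.2 against 13.8 CPM, 1.97). The VEGF and guidance list had 11 of 24 members lower, 1 higher and 12 not called (median -1.44). In the matrix and integrin list 8 of 18 were lower and 2 higher (median -1.06): Sparc stood at 132 against 974 CPM (-2.80) and Nid1 at 14.5 against 109 CPM (-2.28), while Fn1, fibronectin, stood at 396 against 100.0 CPM (1.88) and the integrin Itga4 at 99.2 against 3.91 CPM (2.97). The matrix list had a median of -0.44 in library 5 and -1.02 in library 6, where Sparc stood at -1.40 and -2.32. The ratios of Fn1 (2.65 and 2.59), Vwf (2.69 and 3.07) and Procr (2.37 and 2.21) were larger within these libraries than pooled. Those of Ifitm1 (4.05 and 4.05), Kdr (-2.92 and -2.72) and Efna1 (-1.90 and -2.13) were smaller, so that Spi1 (4.76 and 5.27) and Runx1 (4.22 and 4.29) lay above Ifitm1 there.

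Metabolic and cell cycle lists held few called genes, although some of their medians lay low among the random lists. In the glycolysis list 3 of 15 genes were lower, among them Pkm (447 against 1223 CPM, log2 ratio -1.43) and the glucose carrier Slc2a1 (-1.70). Its median was -0.59, with 0.115% of random lists below it, and -0.70 in each of libraries 5 and 6. In the cholesterol synthesis list 2 of 15 were lower, Fdft1 (-1.47) and Cyp51 (-1.04). The median of this list was -0.72, with 0.01% of random lists below it, and -0.74 and -0.94 in libraries 5 and 6. Cyp51 stood at -0.44 and -0.35 in libraries 5 and 6 and lost its call with equal weight per library (-0.39), in both these libraries alone (-0.40), without library 7 (-0.89) and with the looser filter (-0.98). None of the 20 S phase genes (median -0.03) or the 20 G2/M genes (median -0.37) was called, and the G2/M median was -0.33 in library 5 and -1.08 in library 6. Of the random lists, 50.6% lay below the S phase median and 0.47% below the G2/M median. Of the Notch list, Notch1 was lower (24.1 against 73.7 CPM, -1.30), and of the BMP and TGF-beta list 4 of 14 were, including Id3 (-2.43) and Bmp4 (-2.37). Within libraries 5 and 6 Id3 stood at -0.96 and -1.18, and Eng, another of the 4, lost its call at -0.70 in these libraries alone. Hoxa9 of the Hox list was higher (90.6 against 24.9 CPM, 1.53), as was the adhesion receptor Cd44 (3.03), which lost its call in libraries 5 and 6 alone (2.27). Cd44 still met the size there but not the level of 50 CPM, with 34.2 and 52.8 CPM in cluster 13 of these libraries. Sfrp2 of the WNT list was higher (75.4 against 5.05 CPM), although the median of its 7 measured members was -1.13 and none was called lower. In the inflammatory list Ifitm1 was higher and Nfkbia lower (-1.32), with 11 of 13 members not called (median 0.23). Nfkbia stood at -0.22 in library 5 and lost its call with equal weight per library (-0.85), in libraries 5 and 6 alone (-0.81) and with 3000 variable genes (-0.998). The arterial list had 1 of 11 members lower, Nrp1 (41.7 against 188 CPM, -1.94). Nrp1 stood at -0.20 in library 5 and -1.18 in library 6, and its call was lost with equal weight per library (-0.61) and in these libraries alone (-0.58). The median of the list was -0.68 over all libraries but 0.10 in library 5 and -0.27 in library 6, and the medians of the Notch, cytokine, growth factor, S phase and Hox lists also differed in sign between the pooled cells and at least 1 of these libraries. The retinoic acid list had a median of -0.89, with -0.01 in library 5 and -0.66 in library 6, and none of its 7 measured members was called.

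The genes of the sorting antigens are given for reference. Pecam1, Cdh5 and Itga2b entered the clustering and the marker lists, so they are no independent check. Pecam1 (CD31) stood at 67.7 CPM in cluster 13 and 178 CPM in endothelial-like cells, Cdh5 (VE-cadherin) at 154 and 316 CPM, and Itga2b (CD41) at 21.6 and 3.03 CPM. The log2 ratio of Cdh5 was -0.99 pooled but -0.03 and -0.38 in libraries 5 and 6, that of Itga2b 1.28 pooled but 0.10 and 1.20 there, and that of Pecam1 -1.28 pooled and -0.99 and -1.11 there. The name of cluster 13 is fragile. Its cells stayed together when the cells were clustered again in 7 other ways, with 222 to 252 of them in 1 cluster, but the class kept its haematopoietic-like name in 2 of the 7 and that cluster was called endothelial-like in 3, so the comparison has no value in 5 of these settings.

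**Figure D2:**
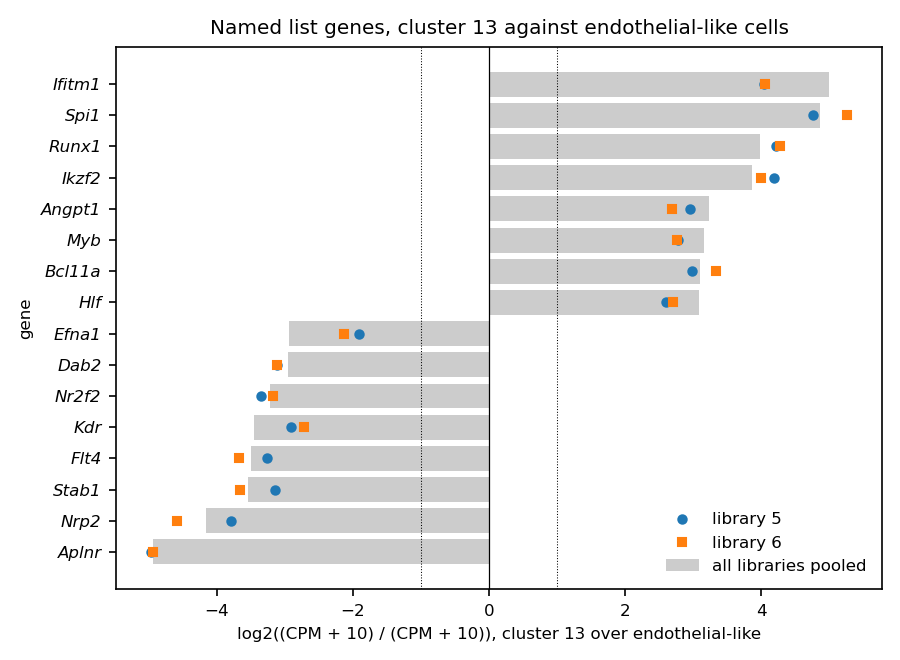
Log2 ratio of CPM (pseudocount 10 CPM) in cluster 13 over endothelial-like cells (horizontal axis) for the 8 highest and 8 lowest list genes called (vertical axis); grey bars are all libraries pooled, points are libraries 5 and 6, and dotted lines mark a log2 ratio of 1 either way. Over the pooled cells Ifitm1 was highest at 5.00 and Aplnr, with no count in cluster 13, lowest at -4.94, a value set by the pseudocount, and both libraries had the sign of the pooled ratio for each gene.

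Endothelial-like cells were then compared with the niche classes, to describe what sets endothelium apart from the other named non-blood classes. Smooth muscle-like cells counted among the niche classes. Kdr had the highest ratio of the list genes called over the pooled cells, while Ramp2 lay above it in libraries 5 and 6 (5.90 and 4.94 against 5.09 and 4.39). Kdr stood at 477 against 4.33 CPM (log2 ratio 5.09), with the other VEGF receptors Flt1 at 250 against 1.38 CPM (4.52) and Flt4 at 121 against 0.466 CPM (3.65). Aplnr stood at 298 against 0.486 CPM (4.88) and Ramp2, a partner of the adrenomedullin receptor, at 820 against 21.1 CPM (4.74). Retinoid-binding proteins and growth factors of mesenchyme were lower, with Crabp1 at 3.85 against 685 CPM (-5.65), Ptn, pleiotrophin, at 3.41 against 447 CPM (-5.09) and Dlk1 at 14.3 against 715 CPM (-4.90). Of 129 list genes at 50 CPM or more, 41 were called higher and 15 lower, with directions checked in libraries 1, 3, 5 and 6. Of 1956 endothelial-like cells, 946 and 904 lay in libraries 5 and 6. Of 6340 niche cells, 1617, 1465, 1418 and 1547 lay in libraries 1 to 4, so the pooled ratios also compare libraries. In libraries 1 and 3 the check rested on 37 and 21 endothelial-like cells.

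The VEGF and guidance list had 13 of 28 measured members higher (median 1.43), including Plxnd1 (194 against 2.77 CPM), and the venous list 6 of 10 (median 1.55). Of the endothelial-to-haematopoietic list, 5 of 11 measured members were higher (median 1.78): Lmo2 (4.12), Lyl1 (3.52), Erg (2.61) and Fli1 (2.11) among them. This list has 20 members, and those below 10 CPM in both classes do not enter its median. Runx1 (0.568 CPM in endothelial-like cells), Spi1 (0.505 CPM), Myb (0.126 CPM) and Hlf (0.568 CPM) were left out in this way. The median therefore does not describe the whole list. In the matrix list 10 of 20 were higher and 1 lower (median 1.32), with basement membrane genes Hspg2, perlecan (165 against 11.3 CPM, 3.04), and Col4a2 (284 against 40.0 CPM, 2.56) higher and Vcan, versican, lower (log2 ratio -3.26). Eng, a TGF-beta co-receptor, was higher (174 against 1.54 CPM). The growth factor list had 4 of 19 higher, including Igf1 (154 against 36.5 CPM, 1.82) and Igfbp4 (1.63), and 3 lower, including Igfbp5 (-2.91). In libraries 5 and 6, 109 of 146 and 104 of 144 niche cells were germ-cell-like, so ratios there compare with another niche than the pooled ones. They were larger for Igf1 (3.60 and 3.12), Igfbp4 (3.18 and 3.35) and Fli1 (3.11 and 3.16). Germ-cell-like cells held Igf1 at 0.517 CPM, Igfbp4 at 5.69 CPM, Crabp1 at 93.6 CPM and no count of Dlk1 or Cxcl12. Ratios were smaller there for Crabp1 (-4.69 and -3.55), Ptn (-3.14 and -2.93), Dlk1 (-3.43 and -2.93), Crabp2 (-3.44 and -2.46), Hoxc8 (-2.46 and -1.999), Vcan (-2.04 and -2.18), Igfbp5 (-1.50 and -2.22) and Cxcl12 (-2.43 and -1.86).

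Of the 24 measured Hox genes, 5 were called lower in endothelial-like cells (median -1.23), including Hoxc8 (1.58 against 158 CPM, log2 ratio -3.86) and Hoxc6 (-3.16), yet the median was 0.00 in library 5 and -0.07 in library 6, against -1.43 and -1.09 in libraries 1 and 3. Hoxc6 stood at -3.55 in library 1 but at -1.64, -1.64 and -1.65 in libraries 3, 5 and 6. Crabp1 and Crabp2 (-4.97) were the 2 of 12 retinoic acid genes called lower, and Dlk1 and the Notch target Hes5 (-2.73) 2 of 10 Notch genes. Hes5 stood at -0.79 and -0.85 in libraries 5 and 6 and lost its call with list genes allowed for clustering (-0.88), at resolution 2 (-2.03) and with equal weight per library (-2.14). At resolution 2 and with equal weight the ratio still met the size. Those calls were lost on the level of 50 CPM or the check of direction. Of the arterial list 2 of 10 were higher (median 1.23), Nrp1 (1.10) and Sat1 (1.14). Both lost the call without doublet removal (0.86 and 1.09) and with the stricter filter (0.87 and 1.06), Nrp1 also with list genes allowed (0.80) and at resolution 2 (0.96), and Sat1 without library 5 (1.09). The Sat1 ratios still met the size, so its calls too were lost on level or direction. The chemokine gene Cxcl12 was lower (-3.11). None of the 18 WNT genes was called, although their median was -1.02, and none of the S phase, G2/M, glycolysis or cholesterol synthesis genes was. Ifitm1 (log2 ratio -3.28) stood at ratios of -7.16 and -6.88 in libraries 5 and 6 and lost its call without germ-cell-like cells (-1.58). TMM scaling would raise the endothelial-like CPM by 0.17 log2 units before the pseudocount is added. Ratios of genes with a low endothelial-like level would therefore shift less.

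The ligands of the fixed pairs were compared over 15 named classes, without the unnamed cells, to describe which cells expressed each most. Among these classes, smooth muscle-like cells had the highest Cxcl12, a chemokine that retains stem cells (464 CPM, 95% interval 406 to 527, against 233 in sclerotome-like cells), Bmp4 (225 CPM, 186 to 270, against 119 in nephric-like cells) and Bmp2 (57.2 CPM, 38.3 to 82.2), from 65 cells. The unnamed cluster 8.3, with 83 cells, had 5 of 7 smooth muscle and 5 of 8 coelomic epithelial or gonadal markers raised. Cxcl12 was among its leading genes, and it did not enter this ranking. Bmp2 fell below 50 CPM without library 2 (33.0 CPM), with the looser filter (29.2 CPM) and with 3000 variable genes (32.6 CPM). Coelomic epithelial or gonadal-like cells had the highest Kitl, at 109 CPM (95.2 to 125), against 66.7 CPM in endothelial-like cells. Mesenchymal-like cells led in Ptn (1070 against 463 CPM in coelomic epithelial or gonadal-like cells), Dlk1 (1329 against 1149 CPM in smooth muscle-like cells) and Mdk, midkine, whose 3801 CPM lay beside 3715 CPM in nephric-like cells, with overlapping library ranges. Igf1 was highest in endothelial-like cells (154 CPM), Angpt1 in cluster 13 (95.2 CPM) and Tgfb1 in megakaryocyte-like cells (150 CPM).

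Of 44 ligands, 18 reached 50 CPM in a class, of which 15 were highest in a niche class, 1 in endothelial-like cells and 2 in blood classes. Most of the 15 classes compared were niche classes, so this count alone shows no niche tendency. The small smooth muscle-like (65 cells) and gut epithelial-like (37 cells) classes were highest for 6 and 3 ligands. Rspo3, an enhancer of WNT signalling, led in sclerotome-like cells (87.9 CPM) and Slit2, a guidance cue, in neural-like cells (121 CPM, against 103 in gut epithelial-like cells). The 37 gut epithelial-like cells led in Shh (132 CPM, 90.5 to 187). Their Sema3c, from 15 counts, stood at 62.1 CPM (34.7 to 102). That interval holds the 38.4 CPM of coelomic epithelial or gonadal-like cells, the next class. Pdgfa stood at 265 CPM (204 to 338) in gut epithelial-like and 262 CPM in germ-cell-like cells, so neither led, and leaving out each library moved the gut epithelial-like level between 203 and 331 CPM. Library ranges lay apart from the next class for 3 ligands and overlapped for 1, and 14 had too few cells per library to compare. A ligand level is no measure of signalling. Of the receptors paired with Cxcl12, Cxcr4 stood at 0 CPM in cluster 13 and 0.126 CPM in endothelial-like cells, with at most 2.59 CPM in any class, and Ackr3 at 0 CPM in both. No value here explains the near absence of Cxcr4. Kit, the receptor of Kitl, stood at 79.8 CPM in cluster 13 and 13.6 CPM in endothelial-like cells. For Bmp4, the receptor Bmpr2 stood at 22.9 and 29.6 CPM and Bmpr1a at 2.78 and 1.14 CPM in these classes.

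**Figure D3:**
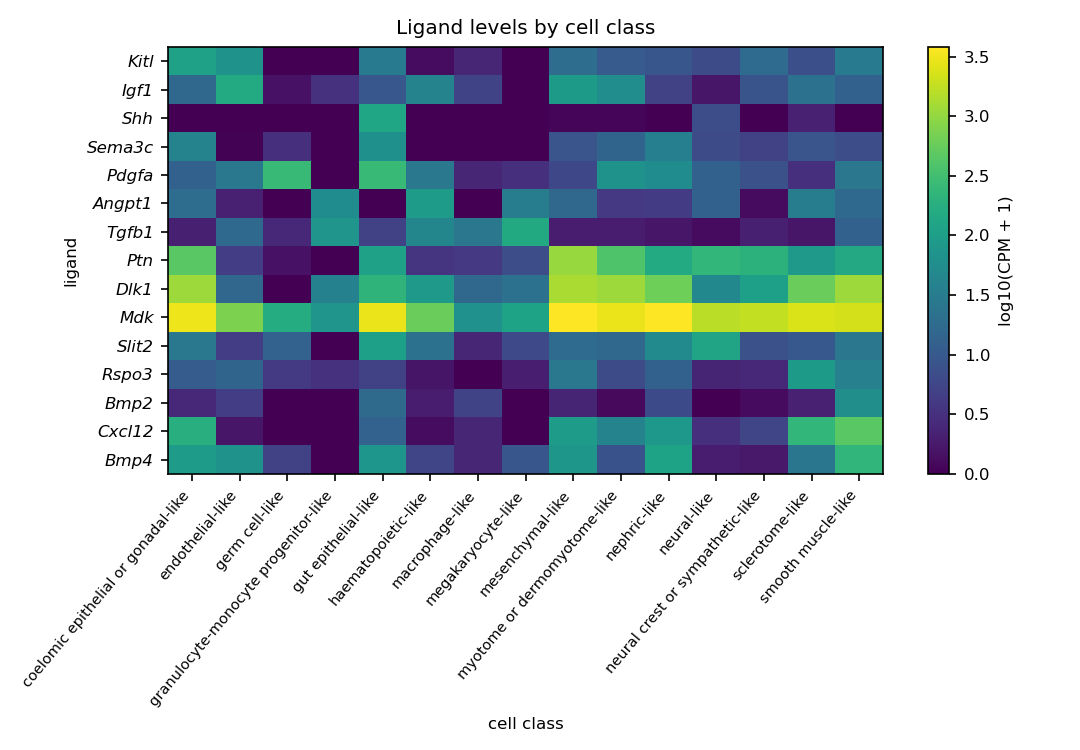
Colour gives log10(CPM + 1) of each named ligand (rows) in the 15 classes of at least 20 cells (columns). Among these named classes Mdk was highest in mesenchymal-like cells at 3801 CPM, and Cxcl12 in smooth muscle-like cells at 464 CPM.

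Within the endothelial-like and haematopoietic-like classes, clusters 1, 5 and 13 were compared. Among arterial genes Nrp1 stood at 147, 248 and 41.7 CPM, Acvrl1 at 38.4, 51.2 and 4.64 CPM and Sat1 at 44.8, 62.2 and 39.0 CPM. Among venous genes Aplnr stood at 282 and 322 CPM in clusters 1 and 5 and had no count in cluster 13, Nrp2 at 296, 159 and 4.02 CPM and Stab1 at 130, 97.6 and 0.927 CPM. Spi1 (0.852, 0 and 298 CPM), Runx1 (0.532, 0.62 and 157 CPM) and Ikzf2 (1.60, 2.33 and 163 CPM) separated cluster 13 from both endothelial-like clusters.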

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

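No paired analysis was possible because each population has 1 sample and no test was made. No named gene that was called changed sign in the settings that gave a value, nor did any list with a median of at least 1 either way (340 values), while the medians of the other lists changed sign in 32 of 540 values. Part of these values could not change. The minimum of 10 CPM and the dropped check of direction alter calls only, and leave ratios and medians as they were. Naming version 4 repeated the values of version 3 wherever it gave the same names. The counts therefore overstate the stability. The main weakness is the name of cluster 13. No haematopoietic-like class existed without doublet removal, with the stricter filter, with list genes allowed for clustering, or at resolutions 0.5 and 2, so these settings give no value for its share or for its comparison with endothelial-like cells. In 3 of them the cells were counted as endothelial-like, at resolution 0.5 they were merged into a cluster of 366 cells called erythroid-like, and at resolution 2 the same 252 cells were called macrophage-like. Naming version 4, added after that name was seen, restored the class at resolution 2 only. What follows on this class therefore covers the settings that kept it. The cause of the changes below was not tested unless stated. The endothelial-like share became 25.1% without doublet removal, 23.8% with the stricter filter and 24.6% with list genes allowed, where it held 252, 222 and 239 of the cluster 13 cells besides others, and the niche share 72.3%, 73.4% and 60.6%. The niche share was 61.5% at resolution 2. These shares were the same under naming version 4. Leaving out each library moved the endothelial-like share between 12.98 and 26.7%, cluster 13 between 1.64 and 3.47%, the niche between 65.8 and 79.6% and germ-cell-like cells between 1.57 and 3.19%, by construction. The count of endothelial-like and haematopoietic-like clusters was 3 at first, 1 at resolution 0.5 and 5 at resolution 2 under naming version 4. With a minimum of 10 CPM, 62 list genes were higher and 50 lower in endothelial-like cells than in the niche, and 26 ligands were highest in a niche class, because more genes were tested. The lists with a median of at most -1 in the cluster 13 comparison, 4 at first, were 2 with equal weight per library, 2 with only the libraries holding both classes and 8 with a pseudocount of 1 CPM; those with a median of at least 1 were 2 with 3000 variable genes. In the niche comparison the lists at or below -1, 3 at first, were 0 with equal weight and 1 with TMM scaling. Of the 41 named genes called in the cluster 13 comparison, 6 lost the call in some setting, among them Nrp1 (-0.61 with equal weight) and Eng (-0.70, likewise), and of 35 in the niche comparison 5 did, among them Ifitm1 (-0.56 without doublet removal). With germ-cell-like cells left out, chosen after seeing the data, 40 genes were higher and 19 lower than in the niche.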

Other observations

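All tests in this part were chosen after the result they bear on had been seen, and so were the genes named in its first 2 paragraphs. Cluster 13 cells differed between libraries in how much endothelial expression they held. In libraries 5, 6, 7 and 8, with 36, 30, 66 and 108 such cells, Cdh5 stood at 307, 245, 137 and 123 CPM, the tight junction gene Cldn5 at 235, 211, 57.5 and 33.1 CPM, Nrp1 at 162, 76.9, 36.1 and 15.7 CPM, Procr at 149, 120, 59.5 and 37.4 CPM and Id3 at 367, 317, 111 and 74.7 CPM. Ikzf1, a lymphoid regulator, went the other way with 17.1, 19.2, 55.6 and 77.7 CPM, and Rac2 with 38.4, 33.6, 51.7 and 108 CPM. Runx1 was similar at 196, 187, 159 and 148 CPM. No label ties these libraries to a sorted population, so these are values of unmapped libraries. Their shares of endothelial-like cells and of cluster 13 differ, as given next. Differences between sorts and between libraries therefore cannot be told apart here.

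The libraries fell into separate sets by their classes. Endothelial-like shares were 2.13, 1.15, 1.39, 1.10, 83.6, 83.5, 4.12 and 5.19% in libraries 1 to 8, cluster 13 shares 0.173, 0.128, 0.265, 0.183, 3.18, 2.77, 68.0 and 70.1%, and niche shares 93.0, 93.6, 93.9, 94.6, 12.9, 13.3, 1.03 and 1.30%. Megakaryocyte-like cells made up 19.6 and 14.9% of libraries 7 and 8. At resolution 2 a further endothelial-like cluster appeared, singled out after its values were seen, with the arterial gap junction gene Gja4 at 147 CPM (126 to 170) against 13.05, 11.8 and 1.93 CPM in the other endothelial-like clusters.

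Cluster 13 carried endothelial and haematopoietic genes together. Doublets of an endothelial and a blood cell cannot exceed both parents. Of the 19 list genes called higher, 8 lay at least 1 log2 unit above the endothelial-like class and every other blood class of at least 20 cells. With the 10 erythroid-like cells also compared, 8 still did. The call itself fixed the distance from endothelial-like cells, the highest other class for Sfrp2 (75.4 against 5.05 CPM), so only the distance from blood classes tests this. Hlf stood at 79.4 against at most 7.31 CPM and Ifitm1 at 406 against 98.0 CPM, both in macrophage-like cells. The 8 genes argue against doublets with these blood classes as the whole cause. They cannot decide on a blood partner without a class apart from cluster 13. The other 11 genes did not, among them Runx1 (157 CPM against 173 CPM in granulocyte-monocyte progenitor-like cells) and Spi1 (298 against 524 CPM in macrophage-like cells). Doublets with cells of the endothelial-like clusters would also bring Nrp2, Aplnr, Stab1 and Flt4, abundant in each of these clusters. These venous-list genes are among the 8 lowest of the comparison. They were picked for near absence from cluster 13 in 1 pair of libraries and read in the other pair. In cluster 13 they stood as a set at no more than 3.88% of any endothelial-like cluster (upper limit) in libraries 5 and 6 and 1.47% in 7 and 8. The endothelial markers, above the highest other blood class, would need at least 17.8 and 5.16% (lower quartiles). An endothelial partner that is low in these genes and has no cluster of its own is not covered. Free RNA from endothelial cells would reach other cells of the same libraries, and the endothelial markers stood at a median of 15.0% of the cluster 13 level in 59 megakaryocyte-like and progenitor-like cells of libraries 7 and 8, with Cdh5 at 0 against 128 CPM but Egfl7 at 63.0% and Icam2 at 56.4%; no biological explanation was tested.

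Germ-cell-like cells sat mostly in libraries 5 and 6, with 213 of 231, although these libraries were otherwise endothelial-like. If they were doublets with endothelial cells they would hold endothelial transcripts, but the 12 endothelial markers stood at a median of 1.09% of the endothelial-like level in the same libraries. Pecam1 was the exception at 58.2 against 179 CPM, and Kit stood at 44.5 CPM over all germ-cell-like cells, while Cdh5 was at 2.28 against 318 CPM. How these cells came to lie in these libraries stays open, and no biological explanation was tested.

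Cluster 13 cells of libraries 5 and 6 held more of several endothelial genes, and free RNA or doublets of the many endothelial cells there would keep their genes in 1 ratio. The 12 endothelial markers would need a median of 20.4% endothelial RNA for their excess over libraries 7 and 8, with a range from -3.83% for S1pr1 to 47.1% for Cdh5. The 4 genes above, abundant in endothelial-like cells, nearly absent from cluster 13 in libraries 7 and 8 and not used for clustering, reached as a set at most 3.88% of any endothelial-like cluster against lower quartiles of at least 9.02% for the markers, which argues against this source as the whole cause. This rule is the third: a minimum of 10 genes, and then the limit of each gene alone (up to 13.9%), had left the source open and were replaced after that was seen, and the limit of each gene alone had also left open the doublets above. Median UMIs also differed, with 6558, 6945, 13825 and 14986.5 per cluster 13 cell in libraries 5 to 8, and no biological explanation was tested.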
